A study of Mus musculus with 4 samples.

How the data were processed

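Total RNA from A3-1 mouse embryonic stem cells was profiled 48 h after siRNA treatment, with 2 replicates given an siRNA against GFP and 2 given an siRNA against Lin28a. Per the labels, 100 ng of RNA was labelled with Cy3 for an Agilent mouse miRNA array. The groups and replicate numbers come from the sample titles. Per the file headers, all 4 arrays were of design 019119, lay on 1 slide and were scanned on 1 occasion, so slide and scan give no batch to test, and a slide block was not fitted. Replicate 1 of siGFP and siLin28a lay at positions 1 and 2, and replicate 2 at positions 3 and 4. Replicate number therefore goes with position on the slide.

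The deposited scanner files hold intensity values on a linear scale. Per the file headers they were made with Agilent Feature Extraction version 9.5.1.1, and per the submitters' processing notes with version 9.5.3.1. In the deposited files, the processed intensity is the mean spot intensity minus a spatial background surface fitted within the array, and it can be negative. The total gene signal of a miRNA is the sum of the total probe signals that Feature Extraction gives (within 1% for 100% of miRNAs with a signal above 10). It is on another scale than the mean spot signals used for probes here, with a median ratio of 0.69 to 0.73 to their sum over a miRNA's probes. The authors' deposited table of the series holds that total gene signal rounded to 1 decimal, with values at or below 0 written as 0 and no scaling between arrays. For signals above 10, 100% of its values lay within 5% of the scanner files' values. Its column medians were 4.7 and 4.7 for siGFP and 6.3 and 9.1 for siLin28a. Coordinates of probe targets are those of build mm9, per the file headers.

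Of 11540 spots per array that were not controls, between 3.21% and 4.32% were left out as outliers by the flags in the files, and no spot was saturated. Processed signals were averaged over the spots of each of 1712 probes. A probe counted as well above background on an array when at least 50% of its spots were so flagged. Each array was divided by the 75th percentile of its signal over the 425 probes well above background on all 4 arrays, which was 226 and 220 for siGFP and 248 and 265 for siLin28a. Values were then floored at 0.0948, the highest over arrays of the lowest scaled signal well above background, and taken to log2. A probe was kept when well above background on both arrays of at least 1 group, which left 477 probes of 231 miRNAs, and the log2 values of a miRNA's kept probes were averaged. Of 192 miRNAs with several kept probes, 16 had probes that differed in sign, and none had probes at least 0.2 from 0 in opposite directions. Differences of dim miRNAs are understated by the floor. Where a miRNA was not well above background on any array of a group, the fold is a bound, computed against the higher, per array, of the lowest signal well above background and the miRNA's own signal.

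Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over 231 miRNAs and a threshold of 0.05. The fit had 2 residual and 1.64 prior degrees of freedom, and the median log2 difference over all tested miRNAs was 0. The 21 lists of miRNAs, the design, the alternatives and the rule for named miRNAs were fixed before the data were examined, except for 2 alternatives added afterwards. The 12 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01. Of these, 3 were called, and 0 were called with an estimated correlation. That correlation rests on 2 residual degrees of freedom, so a list that does not pass with it is weak evidence of no shift. fry, which asks whether the members of a list move one way and makes no comparison with other miRNAs, called 1. Per-array list means were compared by an exact permutation test.

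The text names every tested let-7 member, then up to 10 called miRNAs in each direction by size of change among those whose groups do not overlap, filled to 5 with the largest changes without overlap, given as values, and up to 3 members of each other list with the highest mean level. Members named beyond this rule, such as those of the miR-106b-25 cluster, were chosen after their values were seen.

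The steps were tested on simulated data with the means and spreads of the 231 miRNAs, in 50 runs with 40 changed miRNAs each. The fit recovered 92.7% of miRNAs changed by 1 on the log2 scale and 98.7% of those changed by 2, and 4.92% of its calls were unchanged miRNAs. Lists without a shift were called in 0.667% of tests. These simulations drew miRNAs as independent and used no floor, so they do not cover correlated lists or dim signals. With 40 changed miRNAs per run the adjusted threshold is also easier to pass than in the data, where 2 were called. The recovered shares therefore do not carry over. In the data, let-7g at 1.01 and miR-125a-5p at 0.95 on the log2 scale were not called.

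Alternatives were the scaling over all probes, scaling without let-7 probes, quantile normalization, no scaling, normexp with an offset of 50 on mean and local background intensity, the brightest probe, the total gene signal, the deposited table, no filter, a filter on all arrays, a lower floor, other variance models, the replicate number as a block, an adjusted p threshold of 0.1, and each array left out. The added ones were normexp fitted without outlier spots and the omission of miRNAs at the floor on all arrays. The former was added because normexp gave a higher median signal on 1 array, which had 1 such spot far below its local background. No fit left out that spot alone. Control spots entered no test.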

Results

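MicroRNA levels were measured in A3-1 mouse embryonic stem cells, a cultured line kept in medium with serum and LIF, a cytokine that keeps such cells undifferentiated. Cells received an siRNA against Lin28a or, as the control, an siRNA against GFP, and RNA was taken after 48 h. LIN28A is an RNA-binding protein known to block the maturation of let-7 precursors. Each group had 2 replicates, and each replicate was hybridised to 1 single-colour (Cy3) array, so 4 arrays on 1 slide carry the comparison. The array holds probes for 577 miRNA names, of which 567 are from mouse and 10 are from a mouse herpesvirus. The share of spots well above background was 32.5% and 32.9% on the siGFP arrays and 34.5% and 38.8% on the siLin28a arrays. The number of arrays limits the precision of every value, and because nothing states that the replicates came from separate cultures, p-values measure only the spread between these samples, which may be technical. The level of Lin28a mRNA is not measured by a miRNA array, so the extent of the knockdown cannot be read from these data.

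The comparison of siLin28a with siGFP asks which mature miRNAs depend on LIN28A in embryonic stem cells. let-7a and let-7f, guide strands of the let-7 family that repress growth and stem cell genes, rose with siLin28a. let-7a was at least 2.31-fold higher and let-7f at least 2.39-fold higher, since neither was well above background on either siGFP array. The let-7 family as a list rose by a mean of 0.73 on the log2 scale over 5 tested members (adjusted p = 0.593 with an estimated correlation). All 5 passed the filter through the siLin28a arrays alone, and their siGFP values were set to the floor. This mean could therefore not fall below 0. With no filter on dim probes it was 0.41 over 9 guides. Their siGFP values were set to the floor there too, so that mean could not fall below 0 either. In the other direction, the list of miRNAs of the imprinted Dlk1-Dio3 region fell by 0.24 on the log2 scale over 43 tested members, and the list of miR-17-92 and its paralogous clusters fell by 0.20 over 16. These 3 list calls were made with a preset correlation, and each was lost with an estimated correlation (adjusted p = 0.593 with an estimated correlation for each). That shared value comes from the adjustment over lists. The unadjusted camera p values with an estimated correlation were 0.105 for let-7, 0.207 for Dlk1-Dio3 and 0.293 for miR-17-92. The miR-290-295 cluster, the main embryonic stem cell miRNA cluster of the mouse, had a mean difference of -0.06 over 13 members, which did not pass the test.

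Of 231 miRNAs tested with limma, 2 were higher with siLin28a and 0 were lower at an adjusted p below 0.05, and 57 had an unadjusted p below 0.05, of which 31 were higher and 26 lower. The siLin28a and siGFP arrays did not overlap for 71 miRNAs that were higher and 71 that were lower, 61.5% of those tested against 33.3% by chance. The 33.3% is an average over ways to split the arrays. Since miRNAs move together, the share can lie far from it by chance, and no test was made of it. Of the tested miRNAs, 12 were not well above background on any siGFP array, against 0 for siLin28a. These entered through the siLin28a arrays alone, which favours a higher value, so the counts by direction are not on equal terms. The difference was 1.12 on the log2 scale for let-7a (SE 0.07, limma adjusted p = 0.0210, n = 2 per group) and 1.17 for let-7f (SE 0.07, limma adjusted p = 0.0210, n = 2 per group). All siGFP values of the let-7 members lay at the floor set by the dimmest signal well above background, so their spread there was 0 and these p-values rest on the spread of the siLin28a arrays and of other miRNAs. The count of higher miRNAs was 0 with the scaling taken over all probes, 0 with the normexp background correction, 8 with the total gene signal of each miRNA and 40 with no filter on dim probes. With no filter the prior degrees of freedom were infinite, against 1.64 as reported. With 1 array left out, only differences are given. With 1 siLin28a array the spread came from the siGFP arrays alone, where let-7 values at the floor had a spread of 0. The differences of let-7a and let-7f stayed close to 1 or above it in some alternatives and shrank in others. They were 0.95 (SE 0.09) and 1.00 (SE 0.09) with the scaling over all probes. They were 1.30 and 1.35 without siGFP replicate 1, and 1.14 and 1.19 without siGFP replicate 2. Without siLin28a replicate 1 they were 1.06 and 1.11, and without siLin28a replicate 2 they were 1.18 and 1.22. With normexp they were 0.0045 (SE 0.0086) and 0.025 (SE 0.021), and with normexp fitted without outlier spots, which was added after the data were seen, 0.34 (SE 0.04) and 0.37 (SE 0.04). Both normexp settings add an offset of 50 to each signal, which narrows differences of dim miRNAs. The mean spot signals of the let-7a probes were 4.19 to 9.94 with siGFP and 40.8 to 68.4 with siLin28a.

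The total gene signals, which are not floored, gave the same order of groups for all 9 let-7 guides on the array. They are not scaled between arrays, and the siLin28a arrays were brighter. The rises of 7 guides exceeded 8.68 units, the 95th percentile of 89 other miRNAs in the same siGFP range. Those of let-7c and miR-98 did not, in this comparison chosen after the values were seen. For let-7a the signals were 10.5 and 9.59 on the siGFP arrays and 78.1 and 78.3 on the siLin28a arrays. For let-7f they were 11.0 and 9.99 against 81.8 and 82.6. let-7g had signals of 13.2 and 8.34 against 81.3 and 62.3, and let-7e had 3.77 and 8.89 against 40.2 and 49.6. let-7d had mean signals of 1.77 ± 0.51 (SD, n = 2) with siGFP and 22.9 ± 2.11 (SD, n = 2) with siLin28a. let-7i had means of 2.49 ± 2.04 (SD, n = 2) and 23.0 ± 0.21 (SD, n = 2). let-7b, at 1.27 ± 0.17 against 10.2 ± 1.12 (SD, n = 2 each), let-7c, at 4.48 ± 0.27 against 7.42 ± 2.06 (SD, n = 2 each), and miR-98, at 0.03 ± 0.16 against 2.28 ± 1.87 (SD, n = 2 each), were not called detected on any array. The opposite strands of the let-7 hairpins, 7 on the array, were not detected on any array either, so none was tested.

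**Figure D1:**
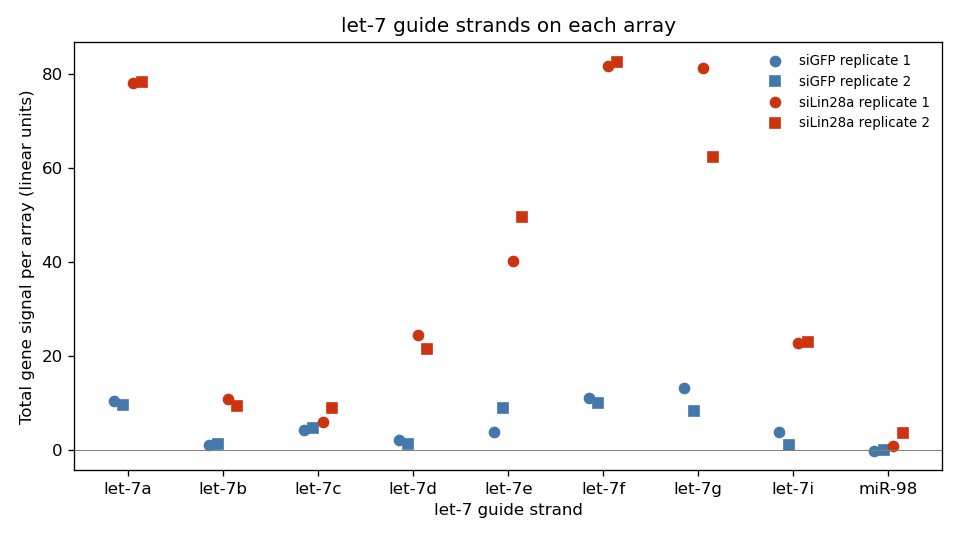
Total gene signal (linear units, vertical axis) of the 9 let-7 guide strands (horizontal axis) on each of the 4 arrays, with blue points for siGFP and red points for siLin28a, circles for replicate 1 and squares for replicate 2. let-7a, let-7f and let-7g lie between 62.3 and 82.6 on the siLin28a arrays and between 8.34 and 13.2 on the siGFP arrays.

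Feature Extraction called 14 miRNAs detected on both siLin28a arrays and on neither siGFP array, and 0 the other way round. Of these 14, 6 were let-7 guides (let-7a, let-7d, let-7e, let-7f, let-7g and let-7i) out of 9 on the array, more than chance gives in Fisher's exact test (two-sided p = 4.87e-09, which treats miRNAs as independent). let-7g was at least 2.15-fold higher (log2 difference 1.01, SE 0.19) and let-7e at least 1.36-fold higher (log2 difference 0.35, SE 0.08), each with a limma adjusted p = 0.159 over all miRNAs. let-7d had a log2 difference of 0.02, since the floor lay far above the siGFP signals of its kept probe and close to its siLin28a signals. Before scaling, the mean spot signals of this probe, which are on another scale than the total gene signals, were 2.73 and 1.77 with siGFP and 24.0 and 20.1 with siLin28a. Adjusted over the list alone, 4 of the 5 tested let-7 members passed, against 2 adjusted over all miRNAs. The let-7 list passed camera (adjusted p = 0.00147 with a preset correlation) and fry (adjusted p = 0.0295), with an adjusted p = 0.593 with an estimated correlation. All 5 tested members entered through the siLin28a arrays alone, so these tests were open to a rise only. The mean of the list was 0.81 with members at their bounds, and it was 0.0059 with the normexp background correction, where the call was lost (camera adjusted p = 0.385, over a range of 6.01e-09 to 0.385 across alternatives), and 2.49 with the total gene signal.

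let-7a, let-7f and let-7d lie close together on mouse chromosome 13 in build mm9, with probe targets at 48633608 to 48633626, 48633258 to 48633278 and 48631447 to 48631465. The probe target of let-7g lies on chromosome 9 at 106081179 to 106081198 and that of let-7e on chromosome 17 at 17967333 to 17967351. The files give 1 locus per miRNA name, and no annotation of exons or introns in that build was used here. let-7 precursors differ in whether they carry a motif bound by the cold shock domain of LIN28. The mean of the tested members with the motif (let-7g and let-7d) minus that of the members without it (let-7a and let-7e) differed between siLin28a and siGFP by -0.22 on the log2 scale. All 4 lay at the floor on both siGFP arrays, which fixed their contrast at 0 there, and let-7d was held near the floor on the siLin28a arrays. The value therefore depends on the floor, and no p-value is given for it. It was 1.25 with the authors' deposited table of total signals, where all 9 guides were tested, so neither its size nor its direction is settled.

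The miRNAs that share a primary transcript with let-7 members were higher on both siLin28a arrays for the 3 members tested. miR-99b had a log2 difference of 0.89 (SE 0.22, limma adjusted p = 0.159), miR-125a-5p of 0.95 (SE 0.27, limma adjusted p = 0.166) and miR-125a-3p of 0.29 (SE 0.17, limma adjusted p = 0.342). Adjusted over the list alone, 2 of the 3 passed, against 0 over all miRNAs. The list had a mean of 0.71 and did not pass camera (adjusted p = 0.0709 with a preset correlation, adjusted p = 0.593 with an estimated correlation). It passed camera in 6 of 20 alternatives, and its mean was -0.0075 with the normexp background correction.

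**Figure D2:**
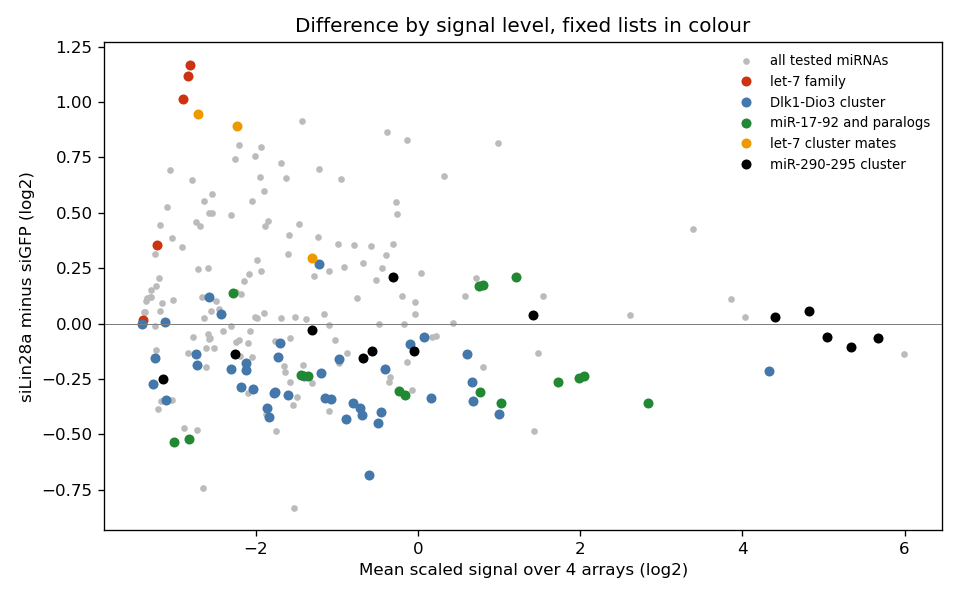
Log2 difference of siLin28a minus siGFP (vertical axis) against the mean log2 scaled signal over the 4 arrays (horizontal axis) for the 231 tested miRNAs, 1 point each, with 5 fixed lists in colour. let-7a and let-7f lie at 1.12 and 1.17 near the low end of the level axis, most Dlk1-Dio3 members lie below 0 across levels, and the brightest members of the miR-290-295 cluster lie close to 0.

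In the Dlk1-Dio3 region, a maternally expressed imprinted cluster, 38 of 43 tested miRNAs had a lower mean with siLin28a, and 30 were lower without overlap of the groups. No member passed on its own, adjusted over the list alone or over all miRNAs, and 14 had an unadjusted limma p below 0.05. miR-154* had a log2 difference of -0.68 (SE 0.16), miR-376b of -0.41 (SE 0.08), miR-127 of -0.35 (SE 0.09) and the bright miR-494 of -0.21 (SE 0.08). The list passed camera (adjusted p = 4.87e-09 with a preset correlation) but not with an estimated correlation of 0.47 among its members (adjusted p = 0.593 with an estimated correlation) nor in fry (adjusted p = 0.210). The exact permutation test of its per-array means gave p = 0.333, the smallest it can give, and the mean of the list was -0.14 without siGFP replicate 2 and -0.05 with no scaling between arrays, where it still passed camera with a preset correlation.

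In the miR-17-92 group of clusters, known to promote proliferation, 12 of 16 tested members were lower and 4 were higher, each without overlap of the groups. The 4 higher ones were miR-106b (0.21, SE 0.08), miR-25 (0.18, SE 0.09), miR-93 (0.17, SE 0.08) and miR-106b* (0.14, SE 0.10), which all belong to the miR-106b-25 cluster. Among the lower ones, miR-19b differed by -0.36 (SE 0.09), miR-20a by -0.25 (SE 0.09) and miR-92a by -0.24 (SE 0.07), all on the log2 scale. No member passed adjusted over the list alone or over all miRNAs. The list passed camera with a preset correlation (adjusted p = 0.0189) but not with an estimated one (adjusted p = 0.593 with an estimated correlation), and it did not pass camera with quantile normalization (adjusted p = 0.117) or with normexp (adjusted p = 0.746), over a range of 0.00323 to 0.746 across alternatives. Its mean of -0.20 was -0.00586 with no scaling between arrays.

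The miR-290-295 cluster had members with mean log2 scaled levels from 5.67 for miR-295 down to -3.14 for miR-291b-3p, which lay close to the floor. miR-295 differed by -0.07 (SE 0.09), miR-294 by -0.06 (SE 0.08) and miR-291a-3p by -0.11 (SE 0.10), and 0 of 13 members passed over the list alone (camera adjusted p = 0.369). Its mean difference of -0.06 was 0.14 with no scaling between arrays. The list for the large cluster in an intron of Sfmbt2 was set by name family. Of its 17 tested miRNAs, 16 have probe targets on chromosome 2 between 10388586 and 10436549 in build mm9, and that of miR-297a is given on chromosome 10. The list had a mean of 0.52 (0.51 without miR-297a) and did not pass camera (adjusted p = 0.0709, and adjusted p = 0.593 with an estimated correlation), though it passed in 13 of 20 alternatives. miR-467b in that cluster differed by 0.86 (SE 0.58), miR-669a by 0.65 (SE 0.53) and miR-466f-3p by -0.13 (SE 0.18), each with overlapping groups. In this list, replicate 1 exceeded replicate 2 by 0.63 with siGFP and by 0.75 with siLin28a on the log2 scale, as large as the difference between groups. Between arrays of the same replicate number, siLin28a exceeded siGFP by 0.59 for replicate 1 and by 0.46 for replicate 2. With the replicate number as a block the list passed camera (adjusted p = 4.71e-05 with a preset correlation), though nothing states that the numbers mark a shared batch. The numbers also go with position on the slide. The mean ranged from 0.147 to 0.901 with 1 array left out.

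**Figure D3:**
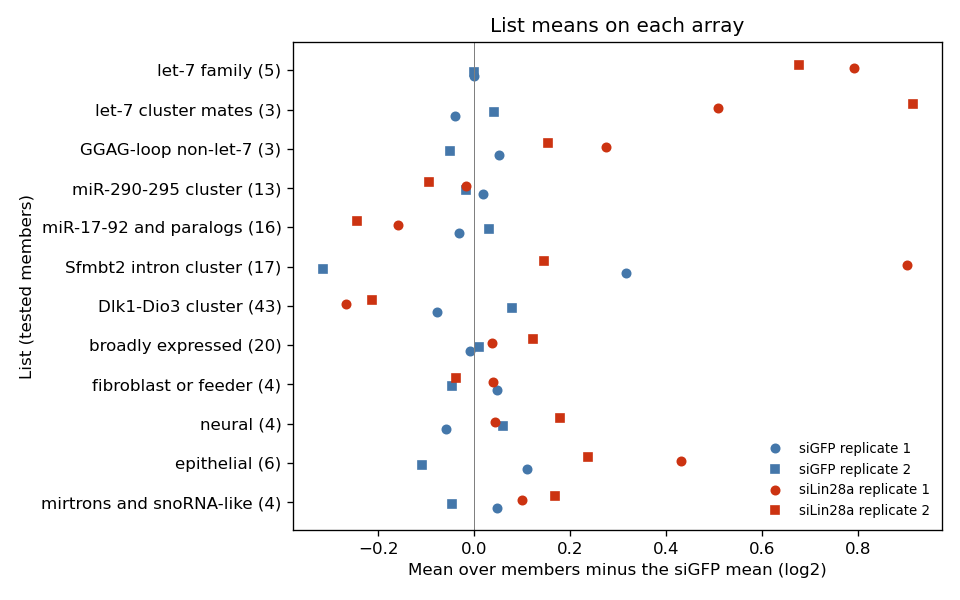
Mean log2 value over the tested members of 12 fixed lists (vertical axis, tested members in parentheses) on each array, minus the mean of the siGFP arrays (horizontal axis), with blue points for siGFP and red points for siLin28a, circles for replicate 1 and squares for replicate 2. Both siLin28a arrays lie to the right of 0 for the let-7 family, whose siGFP values are all at the floor, both siLin28a arrays lie below both siGFP arrays for the Dlk1-Dio3 and miR-17-92 lists, and the Sfmbt2 list separates by replicate number as much as by group.

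Markers of other cell types were examined because embryonic stem cells can differentiate or be grown with feeder cells. Of the fibroblast or feeder list, 4 members were tested, with a mean of 0.00 (camera adjusted p = 0.770), where miR-21 differed by 0.00 (SE 0.20), miR-29a by 0.25 (SE 0.09) and miR-31 by -0.35 (SE 0.08). The neural list had a mean of 0.11 over 4 members (camera adjusted p = 0.369), with miR-124 at 0.03 (SE 0.20), miR-128 at 0.12 (SE 0.12) and miR-219 at 0.17 (SE 0.10). With the scaling over all probes, both means fell below 0, to -0.12 and -0.03. All 6 tested members of the epithelial list, which includes the miR-200 family, had a higher mean with siLin28a. Their mean was 0.33 (camera adjusted p = 0.0632 with a preset correlation and a call in 5 of 20 alternatives, and adjusted p = 0.593 with an estimated correlation of 0.72), and it was -0.017 with normexp. Among the members, miR-141 was at 0.40 (SE 0.20), miR-200a at 0.32 (SE 0.12) and miR-205 at 0.36 (SE 0.22). Of the blood markers only miR-142-3p (-0.09, SE 0.44) and miR-150 (0.11, SE 0.21) were tested. No muscle or endoderm marker and no member of the miR-302 cluster, which is raised in primed pluripotent cells, was well above background on both arrays of a group.

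Of the remaining lists, 20 broadly expressed miRNAs had a mean of 0.08 (camera adjusted p = 0.176), which was -0.09 with the scaling over all probes. miR-16 differed by 0.13 (SE 0.06), miR-22 by 0.21 (SE 0.10) and miR-15b by 0.12 (SE 0.06). The list of miRNAs outside the let-7 family named for a GGAG-like loop motif had a mean of 0.21 over 3 members (camera adjusted p = 0.176), with miR-200c at 0.50 (SE 0.15) and miR-107 at 0.04 (SE 0.07). Its member miR-143, close to the floor, was at 0.10 (SE 0.03, limma adjusted p = 0.202), with a bound of at least 1.09-fold. The miR-34 family, known targets of p53, had 2 tested members, miR-34a at 0.82 (SE 0.16, limma adjusted p = 0.159) and miR-34b-5p at 0.46 (SE 0.20, limma adjusted p = 0.260). Adjusted over the list alone, miR-34a passed. miRNAs made without Drosha had a mean of 0.13 over 4 members (camera adjusted p = 0.771), with miR-877 at 0.66 (SE 0.17), miR-320 at 0.05 (SE 0.12) and miR-1224 at 0.03 (SE 0.11), and that mean was -0.03 with the scaling over all probes. The only viral miRNA tested, mghv-miR-M1-2, lay at the floor on all 4 arrays. The largest decreases without overlap of the groups were those of miR-703 (-0.74, SE 0.29), miR-154*, miR-20a* (-0.54, SE 0.21), miR-18b (-0.52, SE 0.16) and miR-805 (-0.49, SE 0.18), and none passed the limma test.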

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

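All tests of explanations in this part were chosen after the result was seen. Outside the tested miRNAs, 5 were detected on both siLin28a arrays and on neither siGFP array, with scaled total signals above both siGFP arrays. let-7i had a mean total signal of 23.0 with siLin28a against 2.5 with siGFP. miR-362-3p had 24.4 against 14.4, miR-467e* had 18.7 against 11.8, miR-718 had 18.9 against 9.9, and miR-99b*, the opposite strand of miR-99b, had 17.5 against 10.2.

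let-7i belongs with the rise of the let-7 guides. The siLin28a arrays were brighter than the siGFP arrays, which could raise dim signals in general. Among 10000 random sets of 9 drawn from 89 other miRNAs in the same range of siGFP signal, the highest median rise was 7.30 signal units, while the median rise of the 9 let-7 guides was 21.2, which argues against brightness or background as the whole cause. Cross-hybridization among let-7 probes stays open: the rise of let-7c was 4.31% of that of let-7a, but the cross-reactivity of each probe is not known here. Release of let-7 precursors from LIN28A is the explanation the design names, and it stays a hypothesis, since a single siRNA per target leaves effects on other transcripts untested. Another siRNA against Lin28a, with levels of the let-7 precursors, would test it.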

How the results depend on the processing

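Of the alternatives, only normexp fitted without outlier spots and the omission of miRNAs at the floor were chosen after the data were seen. The 2 higher miRNAs, let-7a and let-7f, were again called with scaling without let-7 probes, quantile normalization, no scaling, the brightest probe, both other variance models, the threshold of 0.1 and the omission of miRNAs at the floor. Scaling without let-7 probes left every value as reported, since no let-7 probe was well above background on all arrays. A call at 0.05 also holds at 0.1, so neither of these settings could lose the calls. The count of higher miRNAs was 0 with scaling over all probes, 0 with normexp, 0 with normexp without outlier spots, and 0 with probes well above background on all arrays, where no let-7 member was left to test. The let-7a difference, 1.12 (SE 0.07) as reported, was 0.95 (SE 0.09) with scaling over all probes, a smaller difference with a wider spread. It was 0.0045 (SE 0.0086) with normexp and 0.34 (SE 0.04) with normexp without outlier spots. There the difference itself shrank, and the offset of 50, above the siGFP signals of its probes, narrows differences of dim miRNAs. Without siGFP replicate 1 it was 1.30 and without siGFP replicate 2 it was 1.14, each on fewer arrays. The count of higher miRNAs was 8 with the total gene signal, 8 with the lower floor, 9 with the deposited table and 40 with no filter, the only alternative with lower miRNAs (8). With no filter the prior degrees of freedom were infinite, against 1.64 as reported, so its counts rest on another estimate of spread. The let-7a difference stayed at 1.12 there, with a larger SE of 0.15. The cause of the other higher counts was not tested. With 1 array left out it ranged from 0 to 13 (0 without siGFP replicate 1, 0 without siGFP replicate 2, 13 without siLin28a replicate 1, 7 without siLin28a replicate 2), where the lone array is assumed to vary like the other group. The shift of the let-7 list was 0.0059 with normexp (camera adjusted p = 0.385, over a range of 6.01e-09 to 0.385), and it kept its direction and its call at the preset correlation in the other alternatives that test it, but its adjusted p = 0.593 with an estimated correlation did not pass. As reported, the filter and the floor allowed this list no other direction. The same held in the alternatives that kept this filter and floor. It also held with no filter, where all siGFP values of the guides still lay at the floor. The kept direction in those settings is therefore no separate evidence of a rise. On siGFP replicate 2, 1 outlier spot had a signal minus local background of -1058, and the median normexp signal there was 127 against 63.3 to 65.3 on the other arrays; without such spots it was 62.2 to 63.4 on all arrays. The Dlk1-Dio3 list kept its direction and its camera call at the preset correlation in all alternatives (-0.40 to -0.05), but its adjusted p = 0.593 with an estimated correlation and its fry adjusted p = 0.210 did not pass. The miR-17-92 list missed the threshold with quantile normalization (-0.20), normexp (-0.10) and normexp without outlier spots (-0.14); the cause was not tested. Its mean was -0.37 with scaling over all probes and -0.00586 with no scaling, and it was called in both at the preset correlation, but its adjusted p = 0.593 with an estimated correlation did not pass. The difference between let-7 members, which as reported depends on the floor, was -0.0023 with normexp, -0.0416 with normexp without outlier spots and 1.25 with the deposited table, and ranged from -0.50 to -0.0725 with 1 array left out (-0.50 without siLin28a replicate 1); the cause was not tested. Scaling over all probes moved the median difference of all miRNAs to -0.16 and no scaling to 0.19, so that values within these sizes can change sign with the scaling, though not all did. Replicate numbers are not stated to mark a shared batch, there are only 2 of each, and they go with position on the slide. Same-numbered arrays deviated together (correlation 0.71 across miRNAs, 0.38 without the Sfmbt2 list), and with the replicate number as a block 2 miRNAs were higher and 0 lower. Of 951 values of named miRNAs under alternatives, 851 kept direction and side of the threshold, 10 lost and 24 gained a call, and 66 changed sign or reached 0. Several alternatives left the differences unchanged, so no sign could change there, which raises the kept share. They were the variance models, the replicate block, scaling without let-7 probes and the omission of miRNAs at the floor. Signal over background limits the let-7 values, since no let-7 guide was detected with siGFP.

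Other list means gained a camera call or moved by over 1 SD in some alternatives, and the cause was not tested. These calls were made at the preset correlation, and as reported the Sfmbt2, cluster mate, epithelial and broadly expressed lists each had an adjusted p = 0.593 with an estimated correlation. The Sfmbt2 list passed at 0.361 with scaling over all probes, 0.441 with quantile normalization, 0.116 with normexp, 0.234 with normexp without outlier spots, 0.577 with the total gene signal, 1.01 with the deposited table, 0.321 with no filter, 0.551 with probes well above background on all arrays, 0.585 with the lower floor, 0.524 with the replicate block and 0.556 with miRNAs at the floor left out. The let-7 cluster mates passed at 0.536 with scaling over all probes, 0.257 with normexp without outlier spots, 0.617 with the total gene signal, 0.711 with probes well above background on all arrays, 0.711 with the replicate block and 0.711 with miRNAs at the floor left out. The epithelial list passed at 0.334 with probes well above background on all arrays, 0.334 with eBayes without a trend, 0.334 with the replicate block and 0.334 with miRNAs at the floor left out. The broadly expressed list passed at 0.282 with no scaling. For the miR-34 family, too few to test in the reported analysis, the mean moved to 0.361 with normexp and 0.266 with no filter. For the blood list, too few to test in the reported analysis, the mean moved to -0.166 with scaling over all probes, 0.211 with no scaling and 1.04 with the deposited table. For the viral miRNA, too few to test in the reported analysis, the mean moved to 0.0275 with no scaling, -0.0387 with the total gene signal, 0.158 with the deposited table and 0.226 with the lower floor. For let-7 members with the motif, too few to test in the reported analysis, the mean moved to 0 with normexp, 0.143 with normexp without outlier spots, 2.32 with the total gene signal, 3.24 with the deposited table, 0.204 with no filter and 1.15 with the lower floor. For let-7 members without the motif, too few to test in the reported analysis, the mean moved to 0.564 with scaling over all probes, 0.591 with quantile normalization, 0.919 with no scaling, 0.00227 with normexp, 0.185 with normexp without outlier spots, 0.953 with the brightest probe, 2.66 with the total gene signal, 1.99 with the deposited table, 0.491 with no filter and 1.45 with the lower floor. Where enough members were tested, the miR-34 family passed camera at the preset correlation with no filter (adjusted p = 0.00107) and without siLin28a replicate 1 (adjusted p = 0.0290), the members with the motif passed with the total gene signal and the deposited table, and those without it with the deposited table and no filter. With 1 array left out, these means ranged from 0.147 to 0.901 for the Sfmbt2 list, from 0.239 to 0.450 for the epithelial list, from -0.0325 to 0 for the viral miRNA, from 0.255 to 0.652 for let-7 members with the motif and from 0.720 to 0.917 for let-7 members without the motif. The Sfmbt2 list passed without siGFP replicate 1 and without siLin28a replicate 2, and the epithelial list without siGFP replicate 1.

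Of the values that changed sign or reached 0, none had passed the test over all miRNAs or lists as reported. However, let-7e, let-7g, miR-125a-5p and miR-99b had passed adjusted over their lists alone. The offset, the outlier spots and the floor bear on the normexp values, and other causes were not tested. A value of 0 is that of a miRNA at the floor on every array used. With normexp, values were -0.00750 for the let-7 cluster mates, -0.00191 for the GGAG-like loop list, 0.0162 for the miR-290-295 list, -0.00939 for the broadly expressed list, -0.0399 for the fibroblast list, -0.0357 for the neural list, -0.0174 for the epithelial list, 0 for let-7d, 0 for let-7e, 0 for let-7g and -0.0308 for miR-125a-5p. In the same setting they were -0.00695 for miR-99b, -0.0334 for miR-200c, 0 for miR-143, 0.108 for miR-295, 0.0642 for miR-291a-3p, 0.109 for miR-294, -0.0537 for miR-34b-5p, -0.0701 for miR-29a, -0.0370 for miR-124, -0.0790 for miR-128, -0.0270 for miR-219, -0.0518 for miR-150, -0.0227 for miR-200a and -0.155 for miR-320. With normexp without outlier spots they were -0.0349 for the fibroblast list, -0.0250 for the neural list, 0 for let-7d, -0.0383 for miR-124, -0.0389 for miR-128, -0.0330 for miR-219, -0.0688 for miR-150 and -0.0304 for miR-320. With no scaling they were 0.137 for the miR-290-295 list, 0.137 for miR-295, 0.0949 for miR-291a-3p, 0.141 for miR-294, 0.0682 for miR-466f-3p, 0.202 for miR-21 and 0.114 for miR-142-3p. With scaling over all probes they were -0.0947 for the broadly expressed list, -0.119 for the fibroblast list, -0.0347 for the neural list, -0.0253 for the Drosha-independent list, 0 for let-7d, -0.130 for miR-107, -0.0488 for miR-16, -0.0520 for miR-15b, -0.145 for miR-124, -0.0546 for miR-128 and -0.0688 for miR-150. In the same setting they were -0.147 for miR-1224 and -0.126 for miR-320. With quantile normalization they were -0.0755 for the fibroblast list, 0 for let-7d, -0.0251 for miR-107, -0.0412 for miR-124, -0.00769 for miR-128, -0.0559 for miR-150 and -0.0573 for miR-320. With the deposited table they were -0.0656 for the fibroblast list and 0.000730 for miR-21. With probes well above background on all arrays the value was -0.0329 for the fibroblast list. With the total gene signal they were -0.0120 for miR-107, -0.0298 for miR-124, -0.0464 for miR-1224 and -0.00899 for miR-320. With the brightest probe the value was -0.00708 for miR-1224. With 1 array left out, they ranged from -0.0338 to 0.0701 for the fibroblast list, from 0 to 0.108 for let-7d, from -0.00188 to 0.0934 for miR-107, from -0.130 to 0.00111 for miR-295, from -0.299 to 0.0260 for miR-466f-3p, from -0.177 to 0.196 for miR-21, from -0.186 to 0.247 for miR-124, from -0.00196 to 0.261 for miR-128, from -0.588 to 0.412 for miR-142-3p, from -0.124 to 0.337 for miR-150 and from -0.104 to 0.161 for miR-1224.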

Other observations

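All tests of explanations in this part were chosen after the result was seen, and the miRNAs of the next sentences were picked after their values were seen. The miR-183 cluster, a set of miRNAs best known from sensory organs, had lower values with siLin28a for all 4 tested strands, which lie on chromosome 6 in build mm9. miR-96 differed by -0.49 on the log2 scale (SE 0.10), miR-182 by -0.45 (SE 0.16), miR-183 by -0.39 (SE 0.18) and miR-183* by -0.48 (SE 0.12), without overlap of the groups and with limma adjusted p values from 0.159 to 0.265. In the other direction, miR-7a differed by 0.83 (SE 0.16), miR-7b by 0.53 (SE 0.10) and miR-29c by 0.60 (SE 0.12), each with a limma adjusted p = 0.159.

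The lower values of the Dlk1-Dio3 miRNAs may reflect a dependence of the difference on signal level. Among 10000 random lists of 43 other miRNAs matched on level, the lowest median log2 difference was -0.11, above the median of -0.27 of the Dlk1-Dio3 list, which argues against that dependence. Variation between cultures that moves the whole cluster stays open, because with 2 arrays per group such variation cannot be told apart from the siRNA. The adjusted p = 0.593 from camera with an estimated correlation does not decide it, since that correlation rests on 2 residual degrees of freedom. An effect of Lin28a on the cluster is a hypothesis that was not tested here; more cultures per group, with another siRNA against Lin28a, would decide between them.

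miR-99b, let-7e and miR-125a lie next to each other on chromosome 17 in build mm9, with probe targets from 17967165 to 17967840. The log2 ratios of scaled total signals were 0.89 for miR-99b, 1.05 for miR-125a-5p, 0.57 for miR-99b*, 2.61 for let-7e and 0.31 for miR-125a-3p. The 4 strands other than let-7e had a median of 0.73, while 146 other miRNAs in the same range of siGFP signal had a median of 0.0404 (SD 0.40), which argues against a rise general to dim signals. Chance scatter of these strands stays open and was not tested, since they were singled out for being higher. A rise of the primary transcript shared with let-7e is a candidate explanation that stays open: the 3 strands miR-99b*, let-7e and miR-125a-3p were also higher on both siLin28a arrays than on both siGFP arrays, but this was known before the explanation was set, so it is no test of it. A measurement of the primary transcript would decide it.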
